A study of Mus musculus with 4 samples.

How the data were processed

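Chromatin immunoprecipitation followed by sequencing was done on thymus of p53 AD/AD mice at 4 weeks of age, with 2 libraries for p53, 1 for PPAR-alpha and 1 input library, per the labels. The p53 and input libraries were read at 50 nt and the PPAR-alpha library at 75 nt, so antibody and read length changed together. Labels number the p53 libraries without saying that they came from separate mice, so their differences measure the spread between these 2 libraries, which may be technical. The input had no list among the 3 files and is not analysed here.

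The authors deposited, for each ChIP library separately, a list of summits (the base of highest pile-up in each called peak) with a score. The deposited score was read as the −log10 of a p- or q-value, from the form of the lists and the range of their values, which no label states. Bowtie2 2.3.4.2, Picard 2.9.0 and MACS2 2.1.2 are named in the submitters' processing notes, without their roles or settings. The calling threshold, the read numbers, and whether the input served as the control are not given in the sources used here. If it served all 3 lists, its own errors are shared by them and add to their overlap. The depth of each library is thus unknown, and only the number of summits and their scores show how much was called. Scores were used to describe, rank or filter summits within a list.

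The submitters' processing notes name a human build, GRCh38, for mouse tissue. The deposited positions were therefore tested against the RefSeq gene table of the mouse assembly GRCm38.p6. Within 1 kb of a protein-coding gene boundary lay 49.2% of the summits of p53 replicate 1, 49.0% of replicate 2 and 42.0% of PPAR-alpha. After moving all summits by 5 to 50 kb in either direction these shares were between 6.38% and 8.20%. The unmoved positions gave the highest share on 19 of 19 autosomes in each list. Positions are given as deposited, counted from 1, and genes were assigned on GRCm38.

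The gene table gives no strand, so the transcription start site of the original plan was replaced by the nearer annotated gene boundary, which is either end of the gene. No genome sequence was used here. The planned p53 and PPAR motif tests, the restriction to CpG-rich promoters and the removal of repeat-masked summits were therefore not run. Genes were the 21887 protein-coding genes of chromosomes 1 to 19, X and Y.

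Summits of different lists within 100 bp counted as shared. Chance was measured with 1000 random placements on the same chromosome and with 1000 placements that kept each summit's distance to a gene boundary but moved it to a random boundary. The permutation test was one-sided and its smallest p is 0.001. The p53 set of both replicates held the replicate 1 summits with a replicate 2 summit within 100 bp, at their midpoint and with the lower score. Shares have exact Clopper-Pearson 95% intervals, which cover counting error only.

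A gene was counted near a summit when either boundary lay within 5 kb. Each of 12 gene lists was compared with all other protein-coding genes by Fisher's exact test, two-sided, for 5 sets of summits, with Benjamini-Hochberg adjustment over the 60 tests. The lists were p53 targets, PPAR-alpha targets, sterol and fatty acid synthesis, glycolysis, the mitochondrial respiratory chain, cytosolic ribosomal proteins, replication-dependent histones, thymocyte identity, and markers of B cells, myeloid cells, thymic epithelium and adipocytes. All members were matched in the gene table, Kitl and Inka2 through older names. Genes are not replicates, neighbouring genes can share a summit, and these tests describe these libraries.

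The grouping, the lists, the 100 bp and 5 kb windows, the tests and most alternatives were chosen before the data were examined. Named genes followed a rule. It took list members of the p53 and PPAR-alpha targets with a summit in both p53 replicates or in p53 and PPAR-alpha. It also took the genes nearest the 10 highest-scoring summits of each set and 2 to 4 high-scoring examples of every other list. Since most of the highest summits had no gene boundary within 5 kb, the 10 highest with a gene boundary in that window were taken, and the highest of all are given by position. A gene that the rule names is not reported here.

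The comparison of sharing within p53 with sharing between p53 and PPAR-alpha divided each share by the number of summits in the partner list. Its interval came from 1000 bootstrap draws of 10 Mb blocks, and this comparison was chosen after the overlaps were seen. The overlap procedure and the list test, but not this bootstrap, were tested on simulated data. With 400 planted shared positions among 3608 summits the overlap procedure found an excess of 399.5, and with none it found −1.82. There was 1 draw per setting, and the simulated summits came from the same boundary placements that measure chance. They therefore do not show how the procedure behaves where summits gather at active promoters. With a true odds ratio of 5, the list test gave a median of 4.96 and called 99.3% of 140 simulated lists among 21887 genes. With a true odds ratio of 1 it called 2.86% of 140. These simulated lists had 40 or more members, genes drawn independently and p without adjustment. Their base rate was above that of the p53 set of both replicates (3.26% of genes). They do not give the power for shorter lists, for that set or after adjustment, nor the false calls where neighbouring genes share summits. Alternatives were other windows, scores of 10 or more, removal of dense clusters (3 or more summits of a list within 10 kb) or of scores of 50 or more, either p53 replicate alone, and other ways to assign genes. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.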

Results

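Binding of p53 and of PPAR-alpha, a nuclear receptor that controls fatty acid oxidation, was mapped in thymus of mice homozygous for the p53 AD allele, whose protein forms dimers in place of tetramers. The lists held 3608 summits for p53 replicate 1, 4767 for p53 replicate 2 and 4070 for the single PPAR-alpha library. The median score, as the authors gave it, was 3.99, 3.62 and 4.70, and the highest was 7038, 7057 and 9205. Most summits were weak, since 71.3% and 73.7% of the p53 summits and 51.9% of the PPAR-alpha summits scored under 5. The PPAR-alpha library has no replicate, and read numbers were not used here.

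Where did p53 and PPAR-alpha summits lie? They gathered at the ends of protein-coding genes in all 3 libraries. Within 1 kb of a gene boundary lay 49.2% of the summits of p53 replicate 1 (95% interval 47.6 to 50.9%), 49.0% of replicate 2 (47.6 to 50.5%) and 42.0% of PPAR-alpha (40.5 to 43.6%). Of the 750 p53 summits found in both replicates, 55.5% did so (51.8 to 59.1%). Random positions on the same chromosomes gave 3.26%, 3.23%, 3.25% and 3.23%, and the permutation p was 0.001 for each set, the smallest that 1000 placements can give. Intergenic positions over 5 kb from any boundary held 14.4% and 14.6% of the p53 summits and 19.6% of the PPAR-alpha summits.

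**Figure D1:**
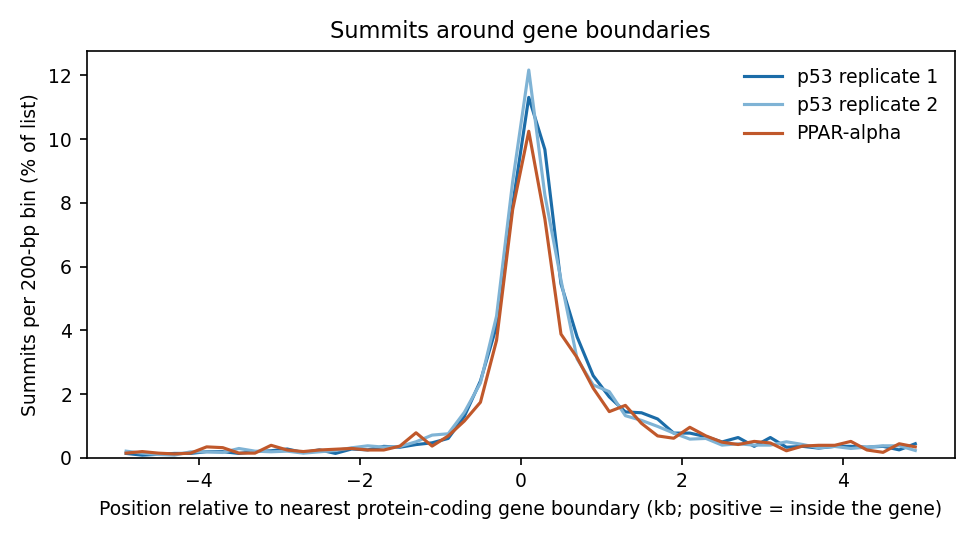
Share of each list's summits (y axis, percent per bin) by position relative to the nearest protein-coding gene boundary (x axis, kb, positive inside the gene), with 1 line per library. All 3 lines peak at the boundary, and 49.2%, 49.0% and 42.0% of the summits lie within 1 kb of it.

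Chromosome X was nearly empty. Outside dense clusters and under a score of 50 it held 0, 3 and 5 boundary summits in p53 replicate 1, p53 replicate 2 and PPAR-alpha, where the autosomal rate per gene predicts 78.6, 100.7 and 72.4. These counts are 0% (exact 95% upper bound 4.70%), 2.98% (0.614 to 8.71%) and 6.91% (2.24 to 16.2%) of that expectation. The 966 protein-coding genes of X had 0, 0.311 and 0.518 boundary summits per 100 genes, and the lowest autosome had 5.67, 7.09 and 4.58. The lack was not particular to X, since the 256 protein-coding genes of Y had 0 in each list.

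**Figure D2:**
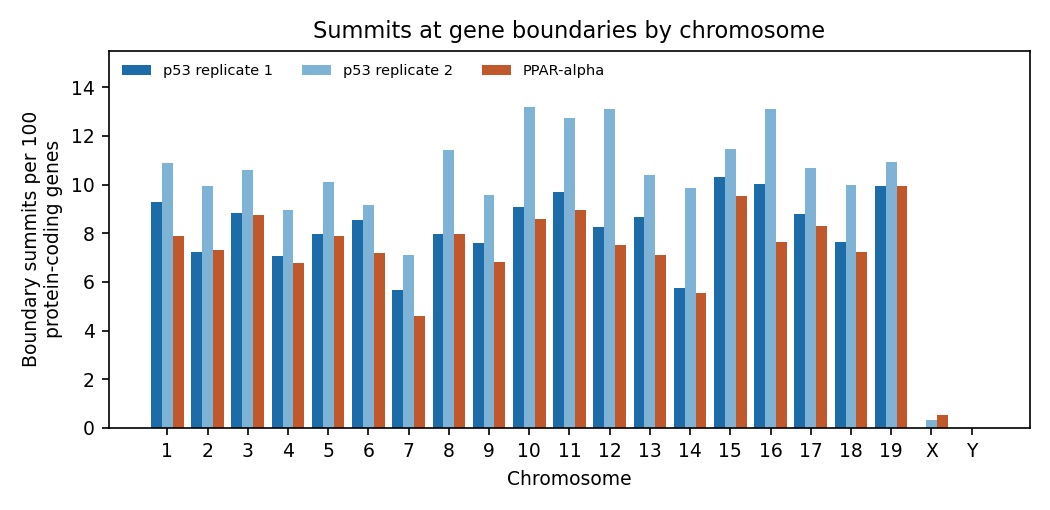
Boundary summits per 100 protein-coding genes (y axis) for each chromosome (x axis), outside dense clusters and under a score of 50, with 1 bar colour per library. Every autosome holds at least 4.58 per 100 genes in each library, X holds at most 0.518 and Y holds 0.

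How far did the p53 replicates share their summits? The strongest shared p53 summits near genes lay at Brox on chromosome 1 (183299342, score 409), Apool on X (112370938, 86.1), Gm42048 on chromosome 8 (121832834, 60.7) and Ubr4, a ubiquitin ligase gene, on chromosome 4 (139380439, 43.7). The centrosomal gene Sfi1 followed with 38.6, then the divergent pair Mrpl32 and Psma2, for a mitochondrial ribosomal protein and a proteasome subunit, with 33.5. Zfp958 (33.5), the Golgi gene Cog6 (24.1), the Integrator subunit gene Ints13 (24.1) and the splicing gene Txnl4a (23.1) completed the 10. Brox, Apool and Gm42048 scored 50 or more in both p53 replicates, and Ubr4 (51.3) and Sfi1 (59.3) in replicate 1 alone. For p53 summits of such scores, repeats or copies that the reference holds fewer times than the genome are a candidate explanation. Their rank does not by itself show p53 binding. The highest scores of all lay far from genes, at position 98667125 of chromosome 2 (7038), 35305413 of chromosome 9 (2455) and 3000418 of chromosome 9 (903). Within 100 bp of a replicate 2 summit lay 750 of the 3608 replicate 1 summits, or 20.8% (19.5 to 22.1%). Placements at random gene boundaries gave 0.566% (permutation p = 0.001, one-sided). The share was 10.2% for replicate 1 summits scoring under 3 and 70.1% for those from 10 to 50. At a window of 500 bp it was 43.5%. The placements drew on both ends of all protein-coding genes, whether or not used in thymus. Shared recovery of active promoters can exceed them, so passing this test does not by itself show shared p53 sites.

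Did p53 and PPAR-alpha occupy the same sites? The strongest PPAR-alpha summits near genes lay at Brox (835), Apool (195), Rab5b (181), the FAD synthase gene Flad1 (136), Sfi1 (114) and the mismatch repair gene Msh6 (96.9). Satb1, a chromatin organiser of thymocytes, and Itprip each had 86.7, Sprtn had 85.5 and Sp140 had 83.0. No p53 summit lay within 500 bp of those of Rab5b and Flad1. A gene named alone here is the nearest to its summit, and some summits, as at Rab5b and Flad1, had other genes within 5 kb. Brox, Apool, Ubr4, Sfi1, Mrpl32 with Psma2, Sprtn, Nup50, Xpo5 with Polh, Yeats4 and the histone methyltransferase gene Kmt2a held the strongest summits near genes that all 3 lists shared. The 7 shared summits with higher scores than Brox lay far from any gene boundary, led by 98667125 of chromosome 2 and 35305413 of chromosome 9. A PPAR-alpha summit lay within 100 bp of 290 of the 750 p53 summits of both replicates, or 38.7% (35.2 to 42.3%), where random gene boundaries gave 0.546%. For all summits of p53 replicate 1 the share was 17.4% (16.2 to 18.7%, chance 0.427%) and for replicate 2 it was 15.6% (14.6 to 16.7%, chance 0.421%), with p = 0.001 in each permutation test. Conversely, 7.13% of the PPAR-alpha summits met a p53 summit of both replicates (6.35 to 7.96%). The same limit of the placements holds here, since they treat all genes alike.

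Over all summits, the p53 replicates shared nearly as many with PPAR-alpha as with each other. Among the highest-scoring summits under 50 and outside dense clusters, sharing was higher within p53. Per partner summit and over all summits, the ratio of sharing within p53 to sharing with PPAR-alpha was 1.02 (bootstrap interval 0.943 to 1.11) from replicate 1 and 1.14 (1.04 to 1.24) from replicate 2. Among the 500 highest-scoring summits of each list outside dense clusters and under a score of 50, the p53 lists shared 124 with each other and 73 or 78 with PPAR-alpha. There the ratio was 1.70 (1.37 to 2.18) from replicate 1 and 1.59 (1.30 to 1.96) from replicate 2, and among the 1500 highest it was 1.38 (1.24 to 1.58) and 1.33 (1.16 to 1.53). With the same exclusions it was 1.07 (0.937 to 1.23) and 1.19 (1.06 to 1.37) within 1 kb of gene boundaries, and more than 5 kb from them 0.969 (0.825 to 1.14) and 1.01 (0.861 to 1.21). Equal rank was not equal score, since 5.38% and 4.30% of the p53 summits and 16.0% of the PPAR-alpha summits scored 10 or more. The size of these ratios may depend on that cut. With full partner lists and dense clusters kept, p53 summits scoring 10 to 50 met the other p53 list in 70.1% and 66.5% of cases from replicates 1 and 2. They met PPAR-alpha in 51.9% and 54.3%. Summits scoring 50 or more met the other p53 list in 75.0% and 73.2% of cases from replicates 1 and 2, and PPAR-alpha in 62.5% and 63.4%. Those shares are not divided by partner numbers. The intervals of the ratios resample genome blocks and do not measure the spread between libraries. Read length differed between the p53 and PPAR-alpha libraries, and the difference between antibodies cannot be separated from it.

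**Figure D3:**
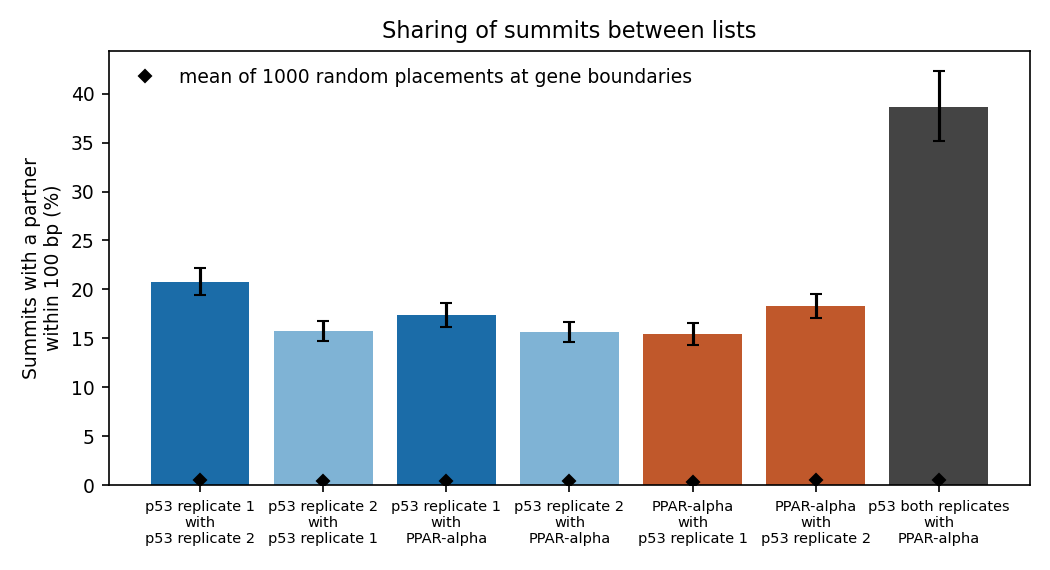
Percent of each list's summits with a summit of another list within 100 bp (y axis), for 7 ordered pairs of lists (x axis). Bars are observed shares with exact 95% intervals, and diamonds are means of 1000 placements at random gene boundaries. The p53 summits of both replicates met PPAR-alpha summits in 38.7% of cases.

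Did dimeric p53 lie near known p53 targets? Of 64 p53 targets, 10 had a summit within 5 kb in both p53 replicates. The cell death receptor gene Fas, the growth arrest gene Gadd45a and the death domain gene Pidd1 had none in the PPAR-alpha list. Trp53inp1, Btg2, Bcl6, Def6, Tap1 and the neighbours Trp53 and Wrap53, which share their summits, had one in all 3 lists. Scores were low, for example 6.24 and 3.62 at Fas on chromosome 19 and 3.34 and 6.72 at Trp53inp1 on chromosome 4 in p53 replicates 1 and 2. In the PPAR-alpha list, Bcl6 had 26.2 and Trp53 13.04. Bbc3, which encodes the cell death protein PUMA, had summits in p53 replicate 1 and PPAR-alpha, and Xpc in p53 replicate 2 and PPAR-alpha. In no library did Cdkn1a or Mdm2, the classical targets for cell cycle arrest and p53 turnover, have a summit within 5 kb. The nearest p53 summit to Cdkn1a lay 8822 bp away in replicate 2 and the nearest PPAR-alpha summit 8809 bp away. The nearest to Mdm2 in any library lay 36450 bp away in p53 replicate 1.

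At 5 kb the p53 targets as a list did not pass the test in any set. In p53 replicate 1, 15 of 64 had a summit (odds ratio 2.06, 1.07 to 3.75, Fisher's exact p = 0.0227, adjusted p = 0.0756), and in replicate 2 also 15 (1.56, 0.814 to 2.84, adjusted p = 0.351). PPAR-alpha had summits near 11 (1.48, 0.697 to 2.87, exact adjusted p = 0.555). Summits within 100 bp in both replicates lay near Fas and Trp53inp1 alone (odds ratio 0.958, 0.113 to 3.62, exact adjusted p = 1). That direction turned when a gene needed only a summit within 5 kb in each replicate, at any distance between them (odds ratio 2.15, 0.973 to 4.27, exact adjusted p = 0.0923). Over the alternatives to the set of both replicates, exact adjusted p ranged from 0.0756, with replicate 1 alone, to 1. Single libraries passed under 1 alternative each: replicate 2 within 1 kb, with 15 genes (2.28, 1.19 to 4.14, Fisher's exact adjusted p = 0.0424), and replicate 1 with summits inside genes added, with 19 (2.48, 1.37 to 4.34, adjusted p = 0.00834). The other replicate did not pass there (adjusted p = 1 for replicate 1 and 0.429 for replicate 2, exact test), and adjusted p reached 1 in both over the alternatives.

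Did p53 and PPAR-alpha lie near PPAR-alpha targets? Acaa1a, a peroxisomal thiolase gene, Cpt1a, which controls fatty acid entry into mitochondria, Slc27a1, a fatty acid transporter gene, and Ucp2, a mitochondrial carrier gene, had summits in all 3 lists. So did Nr1h3 and Txnip. Angptl4, a lipase inhibitor gene, and Crat had them in both p53 replicates and not in PPAR-alpha, and Mlycd in p53 replicate 2 and PPAR-alpha. The highest scores were 37.1 at Ucp2 on chromosome 7 and 30.03 at Slc27a1 on chromosome 8, both in PPAR-alpha. Slc27a1 had 10.7 and 9.40 in p53 replicates 1 and 2, at position 71592146 and 71592071.

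Of the 77 PPAR-alpha targets, 56 had no summit within 5 kb in any library, among them Cd36, Pdk4 and Fgf21, and the list did not pass the test at that window. PPAR-alpha had summits near 12 (odds ratio 1.32, 0.647 to 2.46, exact adjusted p = 0.718), p53 replicate 1 near 11 (1.12, 0.533 to 2.14, adjusted p = 1) and replicate 2 near 14 (1.13, 0.586 to 2.05, adjusted p = 1). The p53 summits of both replicates lay near 5, which were Acaa1a, Angptl4, Cpt1a, Slc27a1 and Ucp2 (2.07, 0.650 to 5.08, exact adjusted p = 0.304). Within 20 kb the list passed, near 26 genes for PPAR-alpha (2.12, 1.27 to 3.47, exact adjusted p = 0.0113) and 10 for p53 in both replicates (2.60, 1.19 to 5.10, adjusted p = 0.0265). Over all alternatives adjusted p reached 1 in both sets.

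Which other gene groups lay near summits? At 5 kb, thymocyte identity genes did so most often, with 24 of 43 in p53 replicate 1 (odds ratio 8.55, 4.49 to 16.5), 30 in replicate 2 (11.9, 5.999 to 24.8) and 30 in PPAR-alpha (16.6, 8.40 to 34.8). Without dense clusters these odds ratios were 3.81, 3.91 and 6.66, and within 20 kb they were 13.3, 15.6 and 40.8. In the p53 replicates they lay under those of ribosomal proteins without dense clusters (5.45 and 9.32) and within 1 kb (5.88 and 4.88 against 6.87 and 9.43). Satb1, Lef1 and Cd2 had scores of 86.7, 23.4 and 18.0 in PPAR-alpha, and Tcf12 had 13.6 and 15.3 in the p53 replicates. Cytosolic ribosomal protein genes had summits in 38 of 81 cases in p53 replicate 1 (6.01, 3.77 to 9.54), 52 in replicate 2 (9.27, 5.77 to 15.2) and 23 in PPAR-alpha (2.84, 1.67 to 4.69), with the highest scores at Rps19 (12.6) and Rpl14 (9.72) in p53 replicate 1. No ribosomal protein gene had a PPAR-alpha summit scoring 10 or more. Genes of the mitochondrial respiratory chain had summits in 21 of 88 cases in p53 replicate 1 (2.12, 1.23 to 3.50), 34 in replicate 2 (3.23, 2.04 to 5.07) and 21 in PPAR-alpha (2.24, 1.30 to 3.72). Among them Atp5b had 54.4 and Uqcrh 40.2 in PPAR-alpha, while Cyc1 took the 71.9 of a summit beside Maf1, its neighbour. Replication-dependent histone genes had summits in 30 of 63 cases in p53 replicate 1 (6.17, 3.63 to 10.4), 24 in replicate 2 (3.15, 1.81 to 5.39) and 15 in PPAR-alpha (2.23, 1.16 to 4.07). In p53 replicate 1 the histone count fell to 18 without dense clusters (2.85, 1.55 to 5.03) and to 15 with the nearest gene only (2.91, 1.51 to 5.29). Histone genes lie close together, so only 16, 13 and 10 distinct summits stood behind these counts, and H1f4 and H2bc6 shared the highest (8.57, PPAR-alpha).

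These 4 lists passed Fisher's exact test in each library, with adjusted p from 3.36e-20 for ribosomal proteins in p53 replicate 2 to 0.0411 for histones in PPAR-alpha. Glycolysis genes passed in PPAR-alpha alone, with 8 of 26 including Pkm and Pfkm (3.17, 1.19 to 7.68, exact adjusted p = 0.0411), beside 5 and 7 in the p53 replicates (adjusted p = 0.718 and 0.465), and the difference itself did not pass (adjusted p = 0.977 for both replicates). The histone, glycolysis and respiratory chain calls of PPAR-alpha ended under some alternatives. So did the respiratory chain in p53 replicate 1 (nearest gene only, or summits inside genes added) and histones in p53 replicate 2 (within 1 kb, or nearest gene only). At scores of 10 or more no list passed in either p53 replicate, and thymocyte identity alone passed in PPAR-alpha. In the p53 set of both replicates, ribosomal proteins passed with 18 genes (8.68, 4.81 to 14.9, exact adjusted p = 7.92e-10) and thymocyte identity with 5 (3.93, 1.20 to 10.04, adjusted p = 0.0442), which fell to 2 without dense clusters (1.67, adjusted p = 0.715; 1.93e-13 to 1 over the alternatives). The respiratory chain had 7 in that set (exact adjusted p = 0.0781) and passed under 5 of 10 alternatives. These included within 1 kb (odds ratio 3.72, exact adjusted p = 0.0190), within 20 kb (2.49, adjusted p = 0.0260) and either replicate alone. Histones had 0 in it, although 14 had a summit within 5 kb in each replicate (3.32, 1.69 to 6.13).

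Sterol and fatty acid synthesis genes did not pass in any set, with 8, 9 and 7 of 41 in p53 replicate 1, replicate 2 and PPAR-alpha, among them Elovl6 in all 3 and Lpin1 and Dgat2 (7.88 each) in PPAR-alpha. Markers of other cells of the thymus did not pass either. B cell markers had 1, 1 and 1 of 15 (Fcer2a and Vpreb1), myeloid markers 1, 2 and 2 (among them Itgam and Cd68), thymic epithelium 0, 4 and 0 (among them Dll4 and Cldn4), and adipocyte markers 1, 1 and 1 (Fabp4 and Cfd). With 15 genes a list, these tests have little power.

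**Figure D4:**
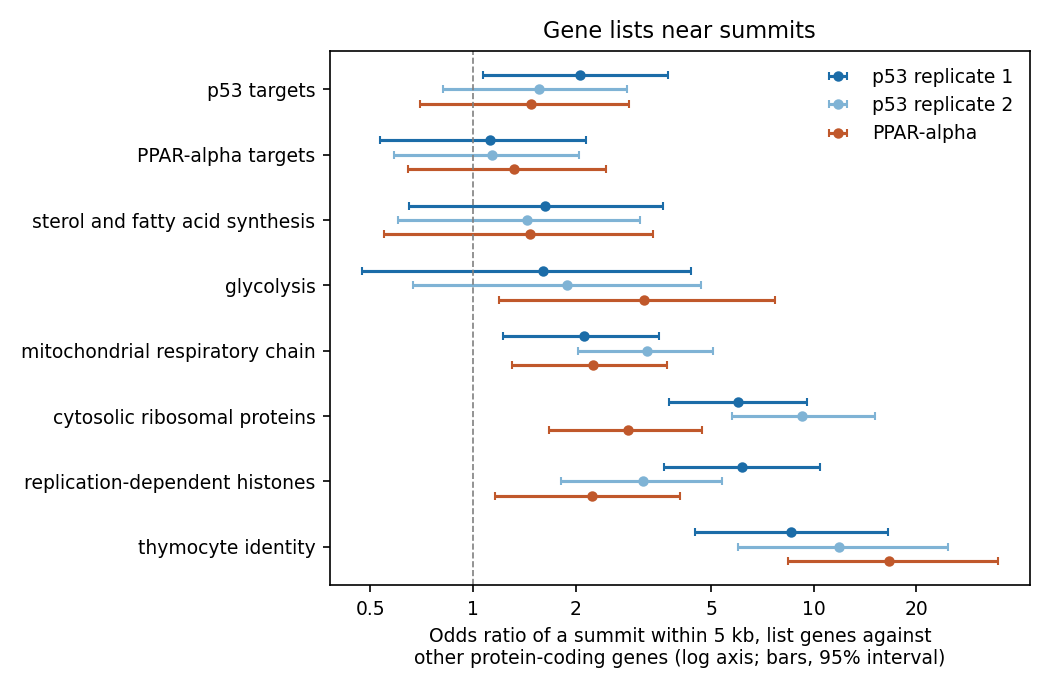
Odds ratio of a summit within 5 kb (x axis, log scale) for 8 gene lists (y axis) against all other protein-coding genes, with 1 point per library and its 95% interval. At this window thymocyte identity has the highest odds ratio in each library, 8.55, 11.9 and 16.6, and the p53 targets stay at or under 2.06.

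How many genes carried both factors? Of 713 genes near a p53 summit of both replicates, 443 (62.1%) also had a PPAR-alpha summit within 5 kb, where independent lists would share 87.7 (odds ratio 13.8, 11.8 to 16.2, Fisher's exact p = 9.54e-228). They included Acaa1a, Cpt1a, Slc27a1, Ucp2 and Trp53inp1. Independence treats all genes alike, whether or not used in thymus, so shared recovery of active promoters can also exceed it. The odds ratio was 14.9 (13.6 to 16.3) between the p53 replicates, 13.6 (12.3 to 14.9) between replicate 1 and PPAR-alpha, and 13.3 (12.1 to 14.6) between replicate 2 and PPAR-alpha. All 3 libraries had summits near 1065 genes, both p53 replicates without PPAR-alpha near 678, and PPAR-alpha alone near 731, of 5408 genes with a summit in any library.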

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

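The tests in this part were chosen after the results were seen, except the planned test of PPAR-alpha targets near p53 summits of both replicates, whose use here was chosen afterwards. Replication-dependent histone genes differed between the libraries: 17 had a summit in p53 replicate 1 and not in PPAR-alpha, and 2 the reverse (odds ratio 7.74 against other genes, Fisher's exact adjusted p = 0.0257 over 36 tests). For p53 replicate 2 the counts were 15 and 6 (exact adjusted p = 1), and neighbouring histone genes share summits, so the p is too small. In p53 replicate 1, 18 of the 30 histone genes with a summit were left without dense clusters, and the contrast was not repeated there. Cytosolic ribosomal protein genes differed between p53 replicate 2 and PPAR-alpha, with 33 against 4 (odds ratio 4.56, exact adjusted p = 0.0257). For p53 replicate 1 they had 23 against 8 (odds ratio 2.62, exact adjusted p = 0.161). Transfer RNA loci differed in the other direction. Of 211 loci, 57 had a PPAR-alpha summit within 1 kb and 32 had one in each p53 list. Against p53 replicate 1, 30 loci had PPAR-alpha alone and 5 had p53 alone (exact p = 2.24e-05), and against p53 replicate 2 it was 32 and 7 (exact p = 7.03e-05). Antibody and read length changed together in each of these contrasts, and PPAR-alpha has 1 library. Between the p53 replicates, 16 histone genes had a summit in replicate 1 alone and 10 in replicate 2 alone (odds ratio 2.73, Fisher's exact adjusted p = 0.161). For ribosomal protein genes these counts were 4 and 18 (0.373, exact adjusted p = 0.478).

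Over all summits, the p53 lists shared nearly as many with PPAR-alpha as with each other (ratio 1.02 and 1.14 per partner summit), while among the 500 highest-scoring outside dense clusters and under 50 they shared more with each other (1.70 and 1.59). Dense clusters and scores of 50 or more do not account for the sharing with PPAR-alpha. Without them 15.3% of the replicate 1 summits still met a PPAR-alpha summit (14.1 to 16.6%). Isolated recurrent positions scoring under 50 were kept, and without a repeat mask or input list they could not be told apart. Ends of protein-coding genes recovered with either antibody do not account for all of it. With the same exclusions 16.3% of the replicate 1 summits over 5 kb from a gene boundary met a PPAR-alpha summit (14.0 to 18.8%), and 15.0% of those within 1 kb did. Promoters of active genes in general stay open, since promoters inside genes and those of noncoding genes were not separated. The biological alternative is that p53 dimers and PPAR-alpha bind the same sites of PPAR-alpha target genes. The 77 listed targets held 4 of the 443 genes near both a PPAR-alpha summit and a p53 summit of both replicates. That argues against the listed targets accounting for most of the sharing, and targets outside the list were not tested. Whether p53 summits favour the listed targets stays open, because their odds ratio near p53 summits of both replicates was 2.07 (0.650 to 5.08). Recovery of open chromatin away from promoters was not tested and stays open too, as the input list and other p53 genotypes were not used here.

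Summits with very high scores recurred across the lists, and 36 of 283 regions with dense clusters had them in all 3. Among these was a run at the thymocyte gene Satb1 (chromosome 17, 51800749 to 51835142, with 15, 12 and 3 summits). Thymocyte identity in PPAR-alpha fell from an odds ratio of 16.6 to 6.66 without dense clusters, so dense runs also lay at genes of this tissue. For p53 summits scoring 50 or more, repeats or copies that the reference holds fewer times than the genome are a candidate explanation. Of those, 2.50% in replicate 1 (upper bound 13.2%) and 0% in replicate 2 (upper bound 8.60%) lay within 1 kb of a gene boundary, where the other summits had 49.7% and 49.4%. For PPAR-alpha the share was 20.9% (11.9 to 32.6%), with 42.4% among the others. A low share cannot tell repeats from binding away from gene ends, which would lower it as well. A run of 48, 59 and 32 summits lay over the Ugt1a genes, Mroh2a, Hjurp and Trpm8 (chromosome 1, 88211822 to 88310482), with 0 in flanks of the same length. Extra copies in these mice are a candidate explanation. At boundaries lay 14.6% of the replicate 1 summits there (upper bound 27.8%), as 14.4% of uniform positions do. That share cannot tell extra copies from other signal that ignores gene boundaries. No biological explanation was tested.

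Few summits lay on chromosome X. Lower use of X genes in thymus was set against genes that every cell uses. Of 7 X-linked ribosomal protein and respiratory chain genes, 0 had a summit in any library, where 103 of 162 autosomal ones did (Fisher's exact p = 0.00113 over the libraries together, 0.0975, 0.00603 and 0.192 in p53 replicate 1, replicate 2 and PPAR-alpha alone). This cannot decide the question, since 7 genes are few and the X deficit was already known. With 6, 9 and 16 summits on all of X over 966 genes, a low count at any 7 of them was likely beforehand. That X is present in 1 copy per cell, which could take weak summits below the calling threshold, cannot be told apart from other causes. PPAR-alpha had 6.91% of the expected X summits (2.24 to 16.2%), an interval that holds the 13.6% of autosomal boundary summits scoring 10 or more and lies below the 74.6% with at least 2 times the smallest score. The p53 replicates had 0% (upper bound 4.70%) and 2.98% (0.614 to 8.71%). Their intervals also lie below the 57.8% and 73.5% with at least 2 times the smallest score. They hold the 4.58% and 3.94% scoring 10 or more. How a score falls with dose is unknown, and the sex of the mice was not used here.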

How the results depend on the processing

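Alternatives that assign the nearest gene only, require a summit near the gene in each p53 replicate, add summits inside genes or drop scores of 50 or more were chosen after the data were seen. No paired analysis was possible because PPAR-alpha has 1 library, so the groups share fewer than 2 replicate numbers. Both overlaps, both boundary shares and the genes shared by p53 and PPAR-alpha kept their direction and side of the threshold under every alternative run (p53 replicates 12.6% to 44.8%, p53 and PPAR-alpha 15.6% to 60.9%). Motif tests, CpG-rich promoters and repeat-masked summits were not run. The number of enriched lists in the p53 set of both replicates, 2, became 0 at scores of 10 or more, 1 without dense clusters, 4 within 20 kb, 4 with a summit in each replicate and 4 with either replicate alone. For PPAR-alpha, 5 became 1 at scores of 10 or more and 3 within 1 kb, 3 with the nearest gene only and 3 with summits inside genes. It became 4 without dense clusters, where histones no longer passed (1.79), and within 20 kb it was again 5, with PPAR-alpha targets in place of glycolysis (2.59). PPAR-alpha targets passed within 20 kb (2.60 for p53, 2.12 for PPAR-alpha), fell to 0 for p53 at scores of 10 or more and to 0.970 for PPAR-alpha with the nearest gene only. The odds ratio of p53 targets in the p53 set, 0.958, rose above 1 within 20 kb (1.47), with the nearest gene (1.33), with a summit in each replicate (2.15), with summits inside genes (1.29) and with either replicate alone (1.56 to 2.06). Histones in the p53 set went from 0 to 3.32 with a summit in each replicate and 3.15 to 6.17 with either alone, and glycolysis from 0 to 1.51 and 1.60 to 1.88. Sterol and fatty acid synthesis turned to 1.07 within 1 kb, 1.03 with the nearest gene, 1.61 with a summit in each replicate, 1.35 with summits inside genes and 1.44 to 1.63 with either alone. At scores of 10 or more the odds ratio was 0 for ribosomal proteins in both sets, for the respiratory chain in the p53 set, and for histones, glycolysis and sterol synthesis in PPAR-alpha, where few summits remain (87 and 651). The cause of the other changes was not tested. Over 170 comparisons of a tested result with an alternative (overlaps, shares, and lists in the p53 set of both replicates and in PPAR-alpha), 16 fell short of a threshold that the result had passed and 10 passed a threshold that it had missed. With 2 p53 libraries, 1 PPAR-alpha library and most scores under 5, the weak summits limit every count.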

Other observations

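The counts in this part were chosen after the results were seen. Among gene classes, summits within 1 kb were most frequent at transfer RNA genes in all 3 libraries: 48 of 408 (11.8%, 8.80 to 15.3%) for p53 replicate 1, 67 (16.4%, 12.96 to 20.4%) for p53 replicate 2 and 116 (28.4%, 24.1 to 33.1%) for PPAR-alpha. Protein-coding genes had 9.21%, 11.9% and 8.80%, long noncoding RNA genes 2.91%, 3.58% and 3.18%, and pseudogenes 0.231%, 0.312% and 0.241%. Joining segments of antigen receptor genes had summits in 8.54%, 9.76% and 12.2% of 82 cases, and variable segments in 0.254%, 1.02% and 2.28% of 394. Each of these shares was computed per gene, and genes that lie close together share summits.

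Summits scoring 50 or more recurred across libraries. Of 40 in p53 replicate 1, 26 had a summit of both other lists within 500 bp (65.0%), as did 26 of 41 in p53 replicate 2 (63.4%) and 50 of 67 in PPAR-alpha (74.6%). The remaining summits did so in 22.5%, 17.3% and 19.6% of cases. The position 35305413 of chromosome 9 was the same base in all 3 lists. Of 283 regions with dense clusters, 36 had them in all 3 lists.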
